A study of Rattus norvegicus with 20 samples.

How the data were processed

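Gene expression was measured by RNA sequencing in the soleus, a slow postural muscle of the lower hind limb, of Sprague-Dawley rats. Poly-A RNA was converted to stranded libraries, per the labels' protocols. The 20 libraries fell into 5 groups of 4 according to the sample labels: uninjured rats, rats with a complete transection of the spinal cord at T2, rats with a 25 g-cm contusion at T2, and rats with the same contusion that swam or walked in shallow water. The labels and the design text describe separate animals. Groups were taken from the labels alone, and each column of the table was matched to its library by its label.

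The deposited values were whole-number counts per gene, not normalised. FastQC 0.10.1, HTSeq and the rn6 genome build are named in the submitters' processing notes; the aligner, the gene annotation and the strand setting of the counting were not given in the sources used here. Genes that overlap, or that have near-identical copies, may share counts. The table held 24613 Ensembl gene identifiers, of which 18618 had a count above 0 in any library, and 0 rows that name no gene. Totals ran from 21165832 to 39729930 counts per library. Pairs of libraries within a group differed by far more than counting error: the chi-square statistic per degree of freedom ran from 28.0 to 549 over 30 pairs, so no library was taken for a copy of another.

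The deposited counts carry identifiers only. The gene table used here for names gave an Ensembl identifier for 0 of its 47357 genes, so 0 of the 24613 identifiers were paired with a symbol. The 36 gene lists fixed before the data were examined, and the rule for named genes, which needed symbols (the 12 highest and 12 lowest per main comparison among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, and 5 and 5 for the other comparisons), therefore could not be applied. In their place 4 identifiers are named, chosen after their values were seen: the genes with the highest and the lowest log2 fold change after transection, the gene with the highest change after swimming, and the 1 gene that differed between the exercise groups, all under the same limits on abundance and overlap. Genes were otherwise described by direction, size of change and abundance.

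Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 20 libraries entered a single fit with a mean per group, which leaves 15 residual degrees of freedom. Libraries were scaled by the trimmed mean of M values, and low counts were removed with filterByExpr at its minimum count of 10, which left 13398 genes. A gene was called changed when its Benjamini-Hochberg adjusted p over these genes was below 0.05; no fold minimum was set. Fold changes are on the log2 scale with a prior count of 0.125, and each standard error (SE) was taken as the size of the log2 fold change divided by the square root of F. Normalised counts are given as CPM, computed with the scaled library sizes. Components were computed on log2 CPM with a prior count of 2. Single measures per library were compared with exact two-sided permutation tests, whose smallest possible p for 4 against 4 libraries was 0.0286.

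The 8 comparisons, their tests and most alternatives were fixed before the data were examined. The alternatives were median-of-ratios scaling, no low-count filter, a mean CPM of at least 1, the replicate number as a block, a fit to the compared groups alone, the Wald test of DESeq2 1.42.0, voom with sample weights in limma 3.58.1, and each replicate left out in turn. Library totals without a scaling factor, and a fit without transection library 3 and swimming library 2, were added after seeing the data. Comparisons that share controls were set beside 20 simulated sets of unchanged groups and were repeated with the controls divided into sets of 2 libraries. A shift of contusion genes with exercise was measured on the 200 genes with the smallest p in 2 contusion libraries against uninjured, and was read as the change with exercise against the other 2 contusion libraries, over all 6 choices.

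The tests were checked on counts simulated for the 13398 genes, with the real means, library sizes and dispersions and 200 genes changed per comparison. For transection against uninjured, edgeR recovered 20.9% of 1.5-fold, 59.7% of 2-fold and 90.9% of 4-fold changes with 5 false calls. On the same counts DESeq2 recovered 32.8%, 64.2% and 90.9% with 19 false calls, and voom 17.9%, 59.7% and 87.9% with 5. With edgeR the shares were 23.9%, 56.7% and 92.4% for contusion against uninjured, and 11.9%, 56.7% and 93.9% for walking against contusion. A simulated shift of 0.50 was read as 0.47, and simulated shifts of 0 as between -0.01 and 0.03. Figures were drawn with matplotlib 3.10.9.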

Results

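RNA sequencing counts were compared in the soleus of rats after injury to the upper thoracic spinal cord. The 5 groups of 4 libraries were uninjured rats, rats with a complete transection, rats with a 25 g-cm contusion, and contused rats that swam or walked in shallow water. Exercise began 2.5 weeks after injury and ran on 5 days a week for 10 weeks. All rats moved to small cages after 4 days. Muscle was taken 8.5 weeks after transection, 11.5 weeks after contusion and 13.5 weeks after contusion with exercise, and the uninjured group is labelled 11.5 weeks, so time differs between most groups along with injury or exercise. Total counts per library ran from 26195066 to 39729930 in uninjured, 31877886 to 36438046 in transection, 22394223 to 35986860 in contusion, 21165832 to 30649862 in swimming and 21445449 to 36604027 in walking libraries. At this depth the median SE of a log2 fold change was 0.20 for transection against uninjured and for walking against contusion.

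The transcriptomes fell apart mainly by transection and then by swimming. The first principal component held 27.6% of the variance, and its 4 transection libraries lay between 31.3 and 93.9 while uninjured libraries lay between -28.5 and -16.5. The second held 18.3%, with swimming libraries between -63.3 and -21.4 and uninjured libraries all above 0, reaching 42.7. Walking library 1 lay at -23.2 on it, among the swimming libraries. Transection library 3 and swimming library 2 stood apart from their groups, at 93.9 on the first component and -63.3 on the second.

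**Figure D1:**
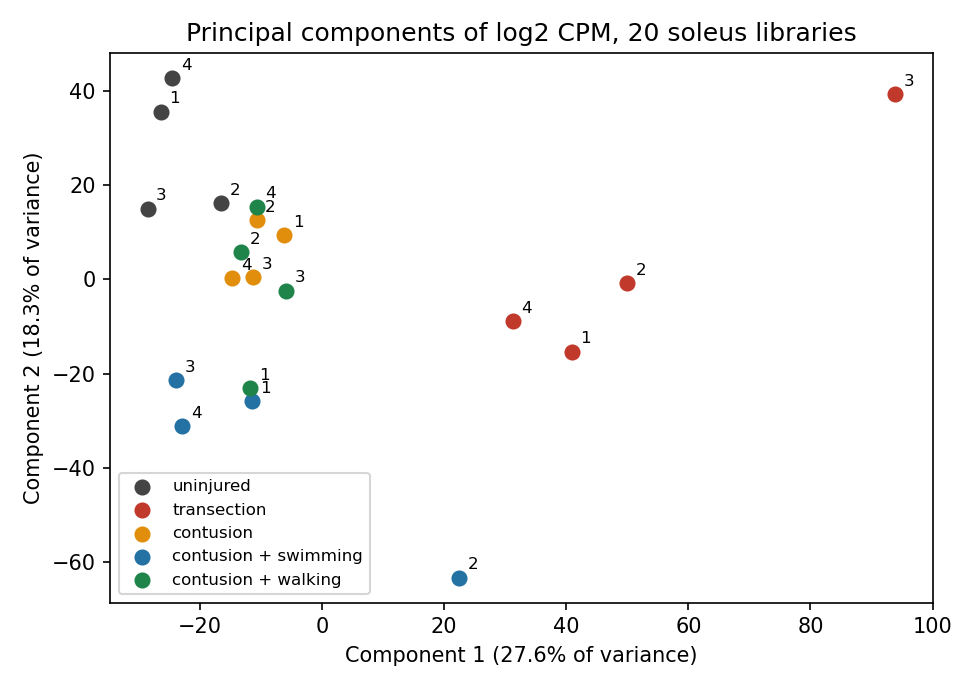
Principal components of log2 CPM for the 20 libraries, with the share of variance on each axis; points are libraries, coloured by group and numbered by replicate. Transection libraries lie to the right, from 31.3 to 93.9 on the first component, and swimming libraries toward the bottom, from -63.3 to -21.4 on the second.

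Transection against uninjured compares a complete transection of the upper thoracic cord with no injury. Labelled time differs as well, at 8.5 and 11.5 weeks. Of 13398 genes tested, 1789 rose and 1976 fell (edgeR quasi-likelihood test, adjusted p below 0.05). Among the genes that rose, 502 did so by more than 2-fold and 92 by more than 4-fold; among those that fell, 814 and 199 passed these sizes. The median log2 change was 0.72 among genes that rose and -0.88 among genes that fell. The gene with the highest change, ENSRNOG00000019745, rose from 4.98 ± 2.45 to 1362 ± 399 CPM (SD, n = 4 each), a log2 change of 8.09 (SE 1.38, edgeR adjusted p = 4.19e-04). The gene with the lowest, ENSRNOG00000046421, was at 3.00 ± 1.17 CPM in uninjured muscle and gave 3 counts over the 4 transection libraries against 436 in uninjured ones, a ratio of 0.00828 per library size with a 95% exact interval of 0.00170 to 0.0244 for counting error alone (edgeR adjusted p = 5.34e-05). The files do not pair these identifiers with gene names. With library totals as the only scaling, the division was 506 higher and 4191 lower, and the median of all genes moved to -0.32, against 0.02 with the scaling used.

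The most abundant transcripts took a larger part of the counts after transection. Of the 50 most abundant genes, 24 rose, 10 fell and 16 did not pass; adjusted over the list alone, 24 rose and 13 fell. This list was chosen from these libraries. The 50 most abundant genes of each library held 57.0 ± 2.91% of its counts after transection and 45.5 ± 1.15% in uninjured muscle (SD, n = 4 each), with no overlap between the groups. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow, and 0.114 after Benjamini-Hochberg adjustment over 8 comparisons. The share was highest in transection library 3, at 60.2%, where 13837 genes had a count.

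Contusion against uninjured compares an incomplete injury with no injury at the same labelled time. No gene passed: 0 genes were called by edgeR's quasi-likelihood test, with a smallest adjusted p of 0.0521, while 1313 genes had an unadjusted p under 0.05. DESeq2 called 100 genes and voom with sample weights 24. Without uninjured library 2 edgeR called 14 genes, and without uninjured library 3 it called 15. ENSRNOG00000019745 stood at 141 ± 104 CPM after contusion against 4.98 ± 2.45 in uninjured muscle (SD, n = 4 each), a log2 difference of 4.82 (SE 1.19) that did not pass (edgeR adjusted p = 0.181). It passed with DESeq2 (adjusted p = 3.36e-04), and with edgeR when transection library 3 and swimming library 2 were left out (adjusted p = 0.0335). In 7.52% of tested genes the groups did not overlap, where chance gives 2.86%.

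Transection and contusion were also compared directly, at 8.5 and 11.5 weeks. After transection 813 genes were higher and 1240 lower than after contusion (edgeR adjusted p below 0.05), with median log2 differences of 0.65 and -0.87. ENSRNOG00000046421 was among the lower genes, at 2.13 ± 0.913 CPM after contusion (SD, n = 4; adjusted p = 3.45e-04). ENSRNOG00000019745 differed by a log2 value of 3.27 (SE 1.10) and did not pass (edgeR adjusted p = 0.0538), though it did with DESeq2 (4.77e-03) and voom (2.22e-03). With edgeR it passed with the compared groups alone (0.0215) and at a mean CPM of at least 1 (0.0439). It also passed without transection library 3 and swimming library 2 (0.0155). With library totals as the only scaling the division was 218 higher and 2293 lower, with the median of all genes at -0.23.

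Genes changed by transection leaned the same way after contusion. With uninjured libraries divided so that selection and reading shared no library, the genes that rose after transection had a median log2 change of 0.22 after contusion and 82.2% of them were above 0, as means over 6 divisions; the genes that fell had a median of -0.18 and 76.8% were below 0. Own medians were 0.88 and -1.02, which selection raises. At adjusted p below 0.05 the comparisons shared 0 genes, with 0 expected of independent lists. This was fixed in advance, since contusion against uninjured had 0 called genes. With divided controls 61 genes were shared at this limit in a single division and 0 in the others. At an unadjusted p under 0.05 in both, a limit chosen after seeing the data, 501 genes were higher in both and 486 lower in both, while 15 were opposite. Independent lists would share 131 and 130. Simulated unchanged groups with the same controls shared 125 on average in the same direction. That number is no like measure, since the simulated transection group had no changed genes. With divided controls 286 to 730 genes were shared in the same direction and 9 to 95 were opposite. Across genes, which are not independent replicates, the log2 changes correlated at 0.540, and at 0.368 with divided controls (0.306 to 0.451). Simulated unchanged groups gave 0.490 (0.466 to 0.522), which for the same reason is no like measure of correlation. The covariance of the log2 changes was 0.171 against a simulated 0.0505.

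**Figure D2:**
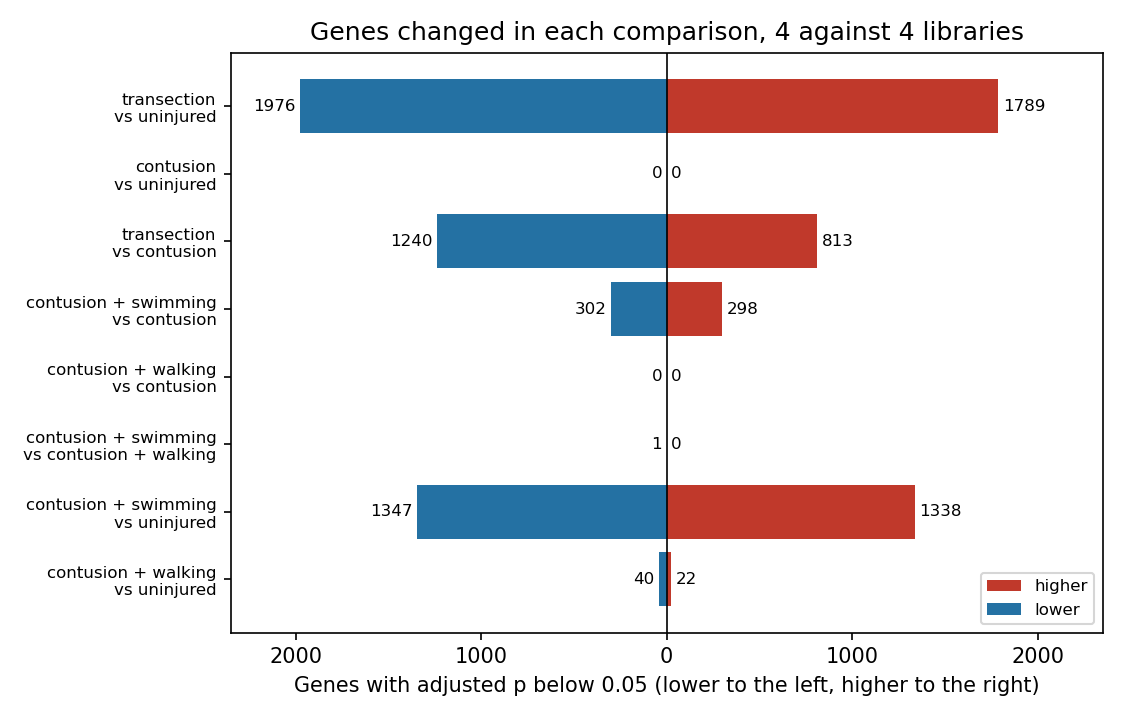
Number of genes with an edgeR adjusted p below 0.05 in each comparison of 4 against 4 libraries; bars to the right count genes higher in the group named first, bars to the left genes lower. Transection against uninjured has 1789 higher and 1976 lower genes, and contusion against uninjured and walking against contusion have 0.

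Swimming against contusion alone asks what this exercise adds to the contused state; it also differs by 2 weeks in time. With swimming 298 genes were higher and 302 lower (edgeR adjusted p below 0.05). Among the called genes, those that rose changed more: 108 by over 2-fold, against 15 of those that fell. Their medians were 0.88 and -0.54 on the log2 scale. These sizes are of genes that passed, and whether abundance affected which genes passed was not tested. The gene with the highest change, ENSRNOG00000050042, rose from 4.48 ± 4.09 to 37.8 ± 37.3 CPM (SD, n = 4 each), a log2 change of 3.09 (SE 0.77, adjusted p = 0.0369); swimming library 2 was at 93.7 CPM, and without it the log2 change was 2.11 (adjusted p = 0.109; without transection library 3 as well, 2.10 and 0.0939). The call was also lost, at log2 changes of 3.05, 2.96 and 2.72, without contusion library 1, 2 or 4 (adjusted p = 0.114, 0.106 and 0.0683). It was lost as well without the low-count filter (0.0605), with the compared groups alone (0.0816) and with the replicate number as a block. Over all alternatives the adjusted p ran from 3.62e-03 to 0.114. ENSRNOG00000023227 fell from 3800 ± 614 to 1090 ± 301 CPM, a log2 change of -1.80 (edgeR adjusted p = 3.21e-03). The number of called genes rested on single libraries: it was 1 without contusion library 1, 65 without contusion library 2, 54 without contusion library 4 and 108 without swimming library 2. With library totals as the only scaling 280 genes were higher and 19 lower, with the median of all genes at 0.19.

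The direction of change after swimming followed transcript abundance. The tested genes were divided by mean abundance into 10 classes of nearly equal size. The median log2 change was 0.16 in class 1, the least abundant, and -0.17 in class 10, the most abundant. In class 10, 13 genes rose and 73 fell, and in class 5, 57 rose and 13 fell. These signs depend on the scaling. With library totals only, 280 genes of all classes were higher and 19 lower, and the median of all genes moved from 0.01 to 0.19. Of the 50 most abundant genes 0 rose, 4 fell and 46 did not pass; adjusted over the list alone, 7 fell. Across genes, which are not independent replicates, the rank correlation of change and abundance was -0.249, and it lay between -0.261 and -0.218 when any single library of these groups was left out. It was -0.104 for walking against contusion (-0.154 to -0.0440 with a library left out), -0.150 for walking against uninjured (-0.183 to -0.0741), -0.221 for swimming against walking (-0.248 to -0.188) and -0.0603 for transection against uninjured (-0.103 to -0.0101). For contusion against uninjured (-0.0704, from -0.114 to 0.0225) and transection against contusion (-0.0165, from -0.0676 to 0.0383) the sign rested on single libraries.

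**Figure D3:**
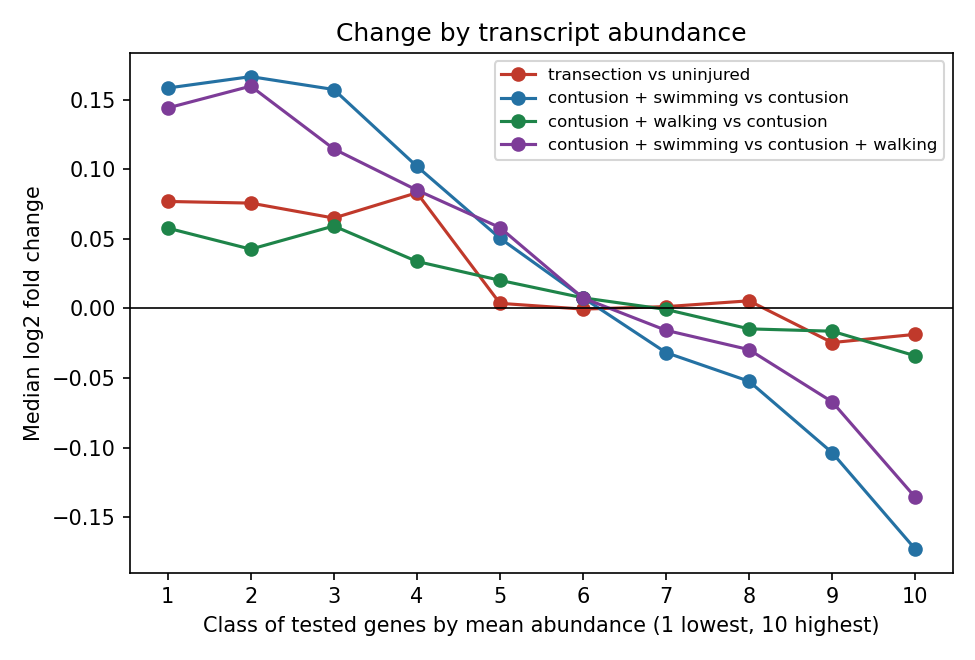
Median log2 fold change (vertical) in each of 10 classes of the tested genes by mean abundance (horizontal, 1 lowest to 10 highest); each line is a comparison. The line for swimming against contusion runs from 0.16 to -0.17.

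Shallow water walking against contusion alone gave 0 called genes with edgeR, DESeq2 and voom, and 0 whenever any single library was left out. An unadjusted p under 0.05 was found for 426 of 13398 genes with edgeR, a smaller share than the 0.05 that chance alone gives. It was found for 617 of 12631 genes with the compared groups alone and for 1319 of 13398 with voom. The groups did not overlap in 2.92% of genes, where chance gives 2.86%. ENSRNOG00000023227 stood at 3517 ± 1006 CPM after walking and 3800 ± 614 after contusion (SD, n = 4 each), a log2 difference of -0.11 that did not pass. Across genes, the changes with swimming and with walking correlated at 0.521. Simulated unchanged groups with the same contusion controls gave 0.477 to 0.546 (mean 0.508). That range is no like measure, since the simulated swimming group had no changed genes. With divided controls the mean was 0.139, from -0.0128 to 0.277 over 6 divisions. The covariance was 0.0761, above the 0.0496 to 0.0605 of the simulated groups (mean 0.0537). With divided controls it was -2.88e-03 to 0.0499.

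The exercise groups, both taken at 13.5 weeks, were compared directly. A single gene passed: ENSRNOG00000023227 was lower after swimming, at 1090 ± 301 against 3517 ± 1006 CPM (SD, n = 4 each), a log2 difference of -1.69 (SE 0.24, edgeR adjusted p = 8.04e-03), and all 4 swimming libraries lay below all 4 walking libraries. It was not called with the compared groups alone (log2 difference -1.70, adjusted p = 0.341) or without walking library 4 (-1.57 and 0.0542). In all, 2052 genes had an unadjusted p under 0.05, DESeq2 called 141 genes and voom 315. Without walking library 1, edgeR called 298 genes. Beside the 600 genes called for swimming and 0 for walking against contusion, the test of the difference itself called this 1 gene.

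**Figure D4:**
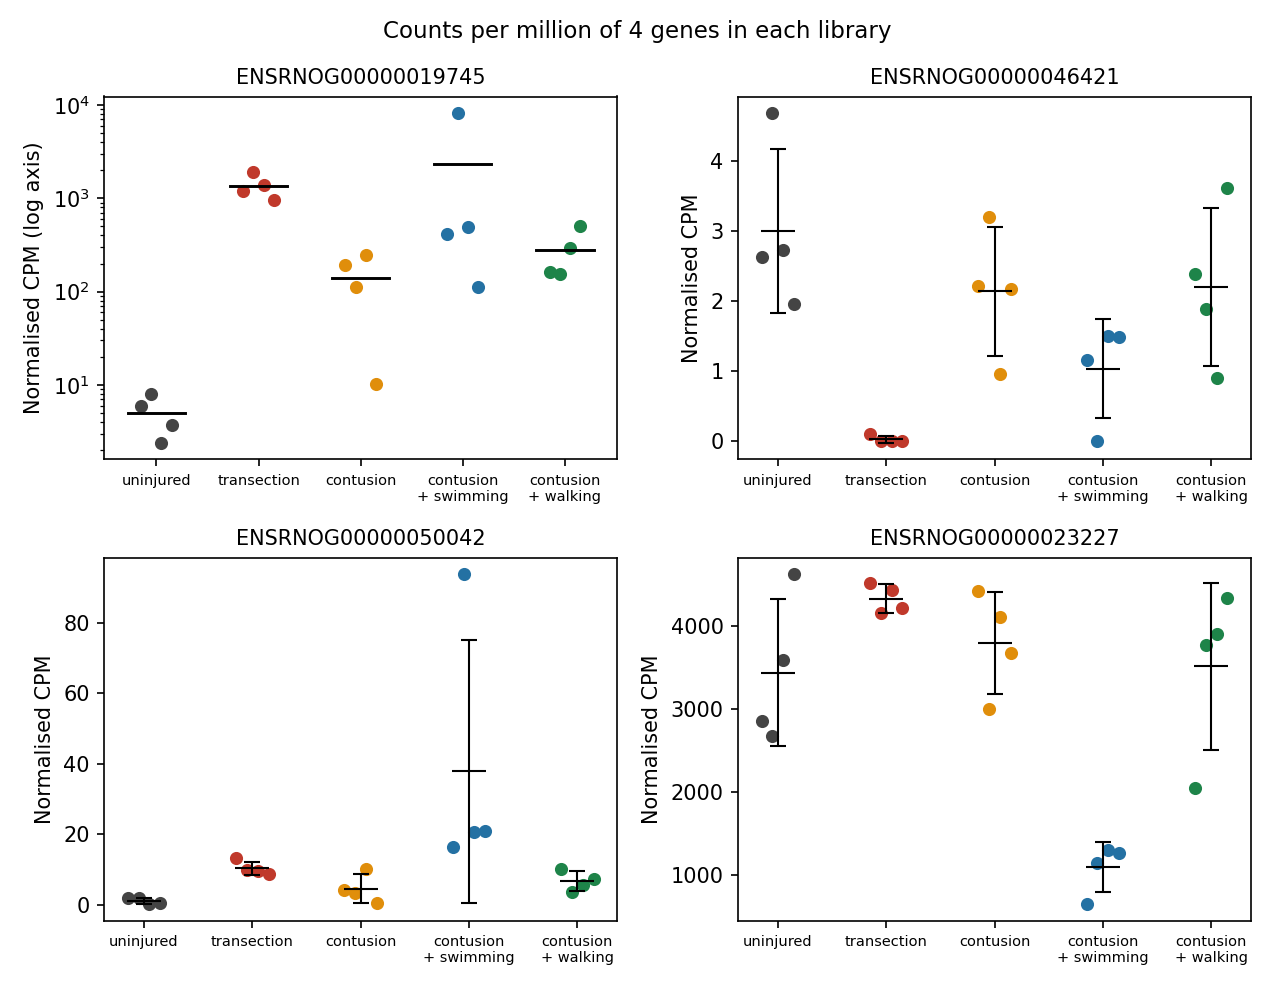
Normalised CPM of the 4 named genes in each library (points) by group; the vertical axis of the first panel is logarithmic and its lines are means, and the other panels show mean and SD (n = 4). ENSRNOG00000023227 lies at 1090 ± 301 CPM after swimming and at 3517 ± 1006 after walking.

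Against uninjured muscle, the swimming group had 1338 higher and 1347 lower genes and the walking group 22 higher and 40 lower (edgeR adjusted p below 0.05). Higher genes with a change over 2-fold numbered 469 after swimming and 12 after walking, and lower genes 228 and 25. Without uninjured library 4 the number called after swimming was 1459. The number after walking was 14 without uninjured library 1, 7 without uninjured library 4, 10, 5 and 30 without walking library 1, 3 or 4, and 374 with DESeq2. ENSRNOG00000019745 stood at 2307 ± 3938 CPM after swimming, where library 2 held 8209 CPM, and at 278 ± 163 after walking (SD, n = 4 each).

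Whether exercise moved the genes of contusion back toward uninjured levels was read on the 200 genes with the smallest p in 2 contusion libraries. After swimming these genes lay farther from uninjured than in the other 2 contusion libraries, by a median log2 value of 0.23 as a mean over 6 choices, with a range of 0.07 to 0.39; 26.8% of them lay nearer, and on 50 genes the value was 0.35. After walking the value was 0.10, with a range of 0.02 to 0.17, and 35.9% lay nearer; it was 0.05 on 1000 genes and 0.15 without walking library 2. The choices share libraries, so no p is given.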

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

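The tests of depth, of the time between groups, of a swap and of replicate numbers, and all counts over other divisions of the libraries, were chosen only after the results they bear on were seen, as was the test of a wrong label, which the position of walking library 1 prompted; the tests of concentrated counts, of swimming library 2 and of thinned swimming libraries were written before.

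Among 65 groups of 4 values examined (library measures and the CPM of the named genes), 6 held a library far from the other 3, where chance gives about 3.25. The scaling factor of uninjured library 4 was 0.982, the next lowest 1.08. The mean rank correlation of contusion library 3 with its group was 0.982, the next lowest 0.986. Walking library 4 held 36604027 counts, the next highest 23665744. ENSRNOG00000046421 stood at 0.0970 CPM in transection library 1 and at 0 in the other transection libraries. Swimming library 2 held 8209 CPM of ENSRNOG00000019745, the next highest 494, and 93.7 CPM of ENSRNOG00000050042, the next highest 20.8. The injuries differed from each other by the direct test at 2053 genes, and the exercise groups at 1 gene, ENSRNOG00000023227.

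Transection library 3 had fewer genes with a count than any other library and the largest share of counts in its 50 most abundant genes, though not in its 10 most abundant (38.1%, against 38.5% in transection library 2). Depth is argued against: thinned to the same total, it kept 13694 detected genes against 14672 to 15751 in the other 19 libraries. Counts taken by a few genes are argued against as well: with the 50 most abundant genes of each library removed and the rest thinned, 13736 genes were detected against 14746 to 15554. A stronger response in that animal and a difference in RNA quality or dissection stay open, and neither was tested.

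After swimming, abundant genes were lower and less abundant genes higher than after contusion alone, with the scaling used. The direction is relative to the other genes, since library totals as the only scaling moved the median of all genes from 0.01 to 0.19. Swimming library 2 by itself is argued against, since the rank correlation of change and abundance was -0.261 without it. Low counts at lower depth are argued against by a value of -0.271 after thinning all 8 libraries to the same total. The later time is argued against as the whole cause, though not as part of it: between swimming and walking, read at the same time, the value stayed at or below -0.188 in every fit without a single library, while walking against contusion, at the same difference in time, gave -0.104. A change with swimming, a difference in tissue make-up and gene length or GC content stay open, the last because the genes could not be joined to an annotation.

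Exchanging contusion library 3 with walking library 1 gave 287 called genes where the groups as labelled gave 0. A swap of these libraries was looked for on the axis from uninjured (0%) to swimming (100%). Walking library 1 lay at 77.1%, outside the 35.9% to 43.1% of the other contusion libraries, where a swap would put it. Contusion library 3, at 57.9%, lay where a swap would put it, inside the 44.0% to 64.4% of the other walking libraries. As labelled, contusion library 3 also lies outside the range of the other contusion libraries. A range of so few libraries therefore cannot decide on a swap. A batch shared by all same-numbered walking and contusion libraries is argued against, since 1 of these 4 pairs had a correlation above 0.1. A wrong label, with walking library 1 a swimming library, was not excluded and gains no support from the position that prompted it: swimming libraries placed on axes made without them lay from 65.3% to 121%, while its 2053 CPM of ENSRNOG00000023227 lay outside both the swimming libraries (648 to 1296) and the other walking libraries (3771 to 4341). An animal that responded to walking as others did to swimming would give the same values, and the label was kept.

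Other divisions of the 8 libraries of each comparison, 35 in all with the labelled one included, were fitted to the compared groups alone. The labelled division gave the most genes for transection against uninjured (3339 genes, highest other 0), contusion against uninjured (28, highest other 1) and transection against contusion (1988, highest other 0). So it did for swimming against contusion (322, highest other 0), swimming against uninjured (1819, highest other 2) and walking against uninjured (142, highest other 14). In each, 1 of the 35 divisions, the labelled one, gave as many genes, the smallest share that 35 divisions allow. This argues against chance without excluding it, since the counts were chosen after the results and were not adjusted over the comparisons. For contusion against uninjured the 28 genes came from the compared groups alone, and the fit to all libraries called 0. For walking against contusion (0 genes, highest other 287) and swimming against walking (0, highest other 40) a labelled count of 0 is matched by all 35 divisions whatever the data, so this count says nothing about chance. By genes with an unadjusted p under 0.05, 14 of 35 divisions reached the 617 of walking against contusion and 4 of 35 the 1587 of swimming against walking. These counts do not argue against chance for either. The 287 and 40 genes, both with walking library 1 moved across, point to a structure of the samples.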

How the results depend on the processing

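The fits with library totals only and without both libraries that stand apart, and the unadjusted limit for shared genes, were chosen after seeing the data. Over 756 recomputed values 0 changed sign as a called value. Transection against uninjured (3050 to 4697 genes), transection against contusion (1391 to 2949) and walking against contusion (0 in all) stayed within 1.5 times under all 17 alternatives. Contusion against uninjured, 0 as fitted, gave 28 genes with the compared groups alone, 100 with DESeq2, 24 with voom, 12 with library totals, 46 without both libraries that stand apart and 0 to 15 with a replicate left out. Swimming against contusion, 600 as fitted, gave 317 without the low-count filter, 322 with the compared groups alone (248 higher, 74 lower), 1203 with DESeq2, 1755 with voom, 299 with library totals (280 higher, 19 lower) and 1 to 504 with a replicate left out. Swimming against walking, 1 as fitted, gave 0, 141 and 315 with the compared groups alone, DESeq2 and voom, and 0 to 298 with a replicate left out. Swimming against uninjured, 2685 as fitted, gave 1459 to 2572 with a replicate left out, and 1185 higher and 776 lower genes with library totals, which moved the median of all genes to 0.12. Walking against uninjured, 62 as fitted, gave 41 without the filter, 142 with the compared groups alone, 374 with DESeq2, 388 with voom, 318 without both libraries that stand apart, 5 to 75 with a replicate left out, and 10 higher and 47 lower with library totals. Genes shared by transection and contusion, 0 as fitted, numbered 25 with the compared groups alone, 0 to 15 with a replicate left out and 987 at an unadjusted p. Their correlation of 0.540 was 0.387 without the filter, which adds genes with few counts. The shift with swimming, 0.23 as fitted, was 0.35 on 50 genes and 0.18 on 1000. The shift with walking, 0.10 as fitted, was 0.13 on 50 genes, 0.05 on 1000 and 0.07 to 0.15 with a replicate left out, all within its spread over the 6 choices. The cause of these differences was not tested. With a replicate left out some counts rose, to 15 for contusion against uninjured and to 298 for swimming against walking. Whether fewer libraries alone would give such rises was not tested.

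Over all groups, replicate numbers did not pair the libraries: same-numbered libraries correlated at 0.0105 on average and others at -0.00326. In all, 4 of 20 correlated best with their own number. Between swimming and contusion, however, all 4 same-numbered pairs were above 0 (0.0464 to 0.428). Their mean was 0.211, against -0.0689 for other numbers, so a shared batch in those groups was not excluded. With the number as a block, swimming against contusion gave 343 genes, contusion against uninjured 1 and the shared genes 1, and ENSRNOG00000050042 had an adjusted p of 0.0596 for swimming against contusion; the block moved no other count by more than 1.5 times. For the 4 named genes, 514 of 544 values kept their side of the threshold, 20 passed that had not and 10 no longer passed. The tests of the 36 gene lists and their alternatives were not run, since no symbols could be joined. At the real depth and spread, with 4 libraries per group, few small changes were recovered. For walking against contusion it was 11.9% of simulated 1.5-fold changes, 8 of 67 genes. Depth and group size were not varied.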

Other observations

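All of the values in this part were computed after the main results were seen. The size of real change was estimated from pairs of half-size comparisons that share no library, as the covariance of their log2 differences over 11566 genes with a mean of at least 1 CPM. Its square root estimates a typical log2 change, with noise between libraries removed on average but not in each estimate. It was 0.65 for transection against uninjured, 0.23 for contusion against uninjured, 0.30 for swimming against contusion and 0.02 for walking against contusion. With any single library left out, contusion against uninjured lay between 0.19 and 0.27 and walking against contusion between 0.00 and 0.14. A mean covariance below 0 was set to 0 before the root was taken. For walking against contusion the covariance ran from -0.0274 to 0.0179 over 18 pairs. Contusion against uninjured, with 0 genes called by edgeR at an adjusted p (1313 at an unadjusted p, 100 with DESeq2), had a covariance above 0 in all 18 such pairs. These pairs reuse the same libraries and are not independent. Swimming against walking was above 0 in all 18 as well (2.49e-03 to 0.0711), although other divisions of its libraries did not argue against chance.

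On the axis from uninjured (0%) to transection (100%), defined on the 3765 called genes, contusion libraries lay at 29.7 ± 4.98%, swimming libraries at 43.5 ± 21.5% and walking libraries at 31.7 ± 6.86% (SD, n = 4 each). Swimming library 2 lay at 75.2%, and the other swimming libraries between 29.9% and 38.1%. On the axis to swimming, transection libraries lay at 68.1 ± 8.74%, walking libraries at 57.5 ± 16.2% and contusion libraries at 43.7 ± 9.88% (SD, n = 4 each). The exact two-sided permutation p for walking against contusion was 0.171, and 0.386 after Benjamini-Hochberg adjustment over 6 such comparisons. Both axes start from the same uninjured libraries, whose chance values raise every position.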
